A study of Homo sapiens with 69 samples.

How the data were processed

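Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in MCF-7, an estrogen receptor-positive breast cancer cell line that carries gained DNA on parts of chromosomes 1, 17 and 20. The series held 69 libraries, of which 35 were ChIP libraries and 34 were input controls. Cells were kept in medium with charcoal-stripped serum for 48 h and then given vehicle or 10 nM estradiol (E2) for 45 min, per the labels. Deposited peak lists were used for 3 samples, which carried the labels TOP2B ChIP with no treatment given, TOP2A ChIP from vehicle cells (replicate 1) and ZATT ChIP from vehicle cells (replicate 2). TOP2A and TOP2B are the paralogous type II topoisomerases, which pass DNA strands through a transient break, and ZATT (ZNF451) is a SUMO ligase that acts on trapped topoisomerase complexes. The RNA polymerase II, estrogen receptor and RAD21 libraries, and with them the comparisons under siRNA, merbarone and ICRF-187, were not analysed here.

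The submitters' processing notes name Bowtie 1.2.0, MACS2, deepTools and the human build hg19, without a role or an order for the tools. The calling thresholds, the control used, any filter on repeated sequence and any pooling of replicates are not given in the sources used here. Each deposited list held 2 call sets that were told apart by the start of the peak name. The TOP2B list joined a set named TOP2B (274 peaks) and a set named TOP2B_nospike (42380 peaks). The TOP2A list joined a set named TOP2A_n1 (204 peaks) and a set named TOP2B_n2 (1768 peaks), so most peaks of the TOP2A list carried a TOP2B name, and neither the factor of that set nor the treatment of either set could be settled from the peak names. The sample titles give replicate numbers for the TOP2A ChIP libraries and none for the TOP2B ChIP libraries. They do not say which libraries the sets TOP2A_n1 and TOP2B_n2 hold. The ZATT list joined a vehicle set (366 peaks) and an E2 set (367 peaks), which were assigned to the only vehicle and the only E2 ZATT ChIP sample.

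The deposited lists gave 1 integer score per peak, which equalled the −log10 q-value multiplied by 10 and cut to a whole number for 42652 of the 42654 TOP2B peaks and for every TOP2A and ZATT peak. The deposited fold enrichment, a ratio over the background of the peak caller, and the −log10 of the p-value and of the q-value stood in further columns. The lists had no header, so the meaning of these columns was read from the MACS2 column layout and from the values. The highest q-value in any deposited list was 0.0992. Scores and fold enrichments are the authors' own values for each peak and were used only to describe, rank or filter peaks within a list. The peak lists hold no read totals, so the sequencing depth behind each list was unknown, and differences in the number of peaks between lists were not interpreted.

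From the lists it was computed how many peaks of 1 list overlapped a peak of another by at least 1 bp. Shares were given with exact 95% binomial (Clopper-Pearson) intervals, which cover counting error only and treat peaks of the 2 call sets of a list as separate even where they overlap each other. Each overlap was set against the mean of 100 random placements of the same peaks within their chromosomes. The length of a chromosome was taken as the largest peak end in any list, and placements ignored assembly gaps and mappability. Mitochondrial peaks were kept in the overlaps, and since they overlap nearly anywhere when placed on so short a sequence, the overlaps were also computed on the nuclear chromosomes alone. Densities per Mb left out chromosome Y and the mitochondrial genome and carried exact 95% Poisson intervals. Peaks that overlapped were joined into loci where loci were counted. With 1 list per factor, 1 ZATT call set per treatment, and no source that says whether the sets within the TOP2A and TOP2B lists are replicates, no replicate check and no test between groups was made. For the closing comparisons, fold enrichment was set against that of the 50 peaks nearest in score, with 1000 bootstrap draws, and clustering was defined as another peak of the same set within 100 kb.

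The overlap code was tested on simulated peaks before use. With 29.97% of 1972 TOP2A-sized peaks planted on TOP2B peaks, 29.75% were recovered as the excess over random placement, and with 29.88% of 733 ZATT-sized peaks planted, 30.07% were recovered. With none planted, 0.662% of the ZATT-sized peaks came out as excess. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Named loci were the 10 with the highest score in each list and the 10 with the highest ZATT score among loci with peaks of all 3 lists. No annotation of hg19 was used here, so loci were named by position alone, and the planned share of peaks at promoters, the 14 planned gene lists and the 10 planned sequence motifs were not run. A table of RefSeq genes of assembly GRCh38.p14 served only to count neighbouring genes of 1 kind per chromosome, and none of its coordinates were set against the peaks. Alternatives fixed before the data were examined were an overlap of at least 50% of the smaller peak, peak centres within 1 kb, the upper 50% of the peaks by score, peak width in place of score, leaving out chromosomes 1, 17 and 20, random shifts of whole chromosomes, and joining of peaks within 1 kb. The remaining alternatives, such as single call sets, the nuclear chromosomes alone and the removal of loci present in all lists, were chosen after the data had been seen.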

Results

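The binding of topoisomerases and of their partner ZATT was profiled by ChIP-seq in MCF-7 cells, an estrogen receptor-positive breast cancer cell line used to follow the transcriptional response to estradiol. The 35 ChIP libraries comprised 20 for RNA polymerase II, 4 for TOP2A, 4 for the cohesin subunit RAD21, 3 for TOP2B, 2 for the estrogen receptor and 2 for ZATT. Peak lists of TOP2A, TOP2B and ZATT were analysed. TOP2A and TOP2B are the paralogous type II topoisomerases, of which TOP2A is tied to proliferation and TOP2B is present in most cells, and ZATT (ZNF451) is a SUMO ligase known to act on topoisomerase II complexes. The TOP2B list held 42654 peaks with a median width of 245 bp that covered 12.4 Mb of hg19. The TOP2A list held 1972 peaks with a median width of 452 bp that covered 0.925 Mb. The ZATT list held 733 peaks, 366 from vehicle cells and 367 from E2 cells, with a median width of 501 bp, and covered 0.285 Mb. The median fold enrichment over background given by the authors was 3.56 for TOP2B, 2.999 for TOP2A and 4.66 for ZATT. The depth of the libraries was unknown, and no replicates could be told apart in the lists, so all intervals cover counting error only.

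The first question was whether the paralogous enzymes occupied the same places. Of the 1972 peaks in the TOP2A list, 1420 overlapped a TOP2B peak, a share of 72.0% (95% interval 70.0 to 74.0). Random placement of the same peaks gave 1.66% on average, with a range of 1.01% to 2.33% over 100 placements, so the observed overlap was 43.4-fold higher. Peaks of the mitochondrial genome were part of these counts, and they overlap nearly anywhere when placed on so short a sequence. On the nuclear chromosomes alone, 1410 of 1962 TOP2A peaks overlapped TOP2B (71.9%), 57.1-fold above the 1.26% of random placement. The remaining 552 TOP2A peaks lay at a median of 5.03 kb from the nearest TOP2B peak, against 30.99 kb after random placement. In the other direction, 1488 of the 42654 TOP2B peaks overlapped a TOP2A peak, a share of 3.49% (3.32 to 3.67). The TOP2A list joined a call set of 204 peaks that was named for TOP2A and a call set of 1768 peaks that was named for TOP2B. In the set named for TOP2A alone, 180 of 204 peaks overlapped the TOP2B list (88.2%), which was 25.3-fold above random placement, or 59.4-fold on the nuclear chromosomes. In the larger set, 1240 of 1768 peaks did so (70.1%). The 2 sets also differed in score, with medians of 53 and 19, so these shares do not compare factors. Of the 442 lowest-scoring peaks of the set with 1768 peaks, 59.1% overlapped the TOP2B_nospike set. Among its 442 highest-scoring peaks the share was 83.0%. When the TOP2B list was restricted to its smaller call set of 274 peaks, 17.4% of the TOP2A peaks overlapped it.

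The highest-scoring loci of the TOP2A and TOP2B lists were largely held in common. Whether these loci mark binding of the enzymes was not tested. The 10 loci with the highest scores in the TOP2A list and the 10 in the TOP2B list shared 9 members. Which of them ranked first depended on the call set. The locus at chromosome 1 position 91852601 to 91853323 had the highest score in the set named TOP2B_n2 and in the larger TOP2B set, and the second highest in TOP2A_n1 and in the smaller TOP2B set. Its fold enrichment was 11.5 in TOP2A_n1, 12.2 in TOP2B_n2, 11.6 in the smaller TOP2B set and 17.7 in the larger. The locus at chromosome 1 position 121484057 to 121485575, beside the centromere, had the highest score in TOP2A_n1 and in the smaller TOP2B set, with fold enrichments of 6.02 and 6.37. Chromosome 1 position 156186105 to 156186772 had a fold enrichment of 10.03 in TOP2A_n1 and 13.6 in the larger TOP2B set, and no ZATT peak. Loci at chromosome 5 position 71146540 to 71147143, chromosome 11 position 85194815 to 85195391 and chromosome 17 position 33477920 to 33478480 likewise had peaks in all 4 topoisomerase sets and no ZATT peak, with fold enrichments in the larger TOP2B set of 19.1, 17.02 and 16.4. The locus at chromosome 12 position 20704151 to 20704702 had the highest fold enrichment of the TOP2B list, 20.3, and a fold enrichment of 10.9 in TOP2A_n1.

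**Figure D1:**
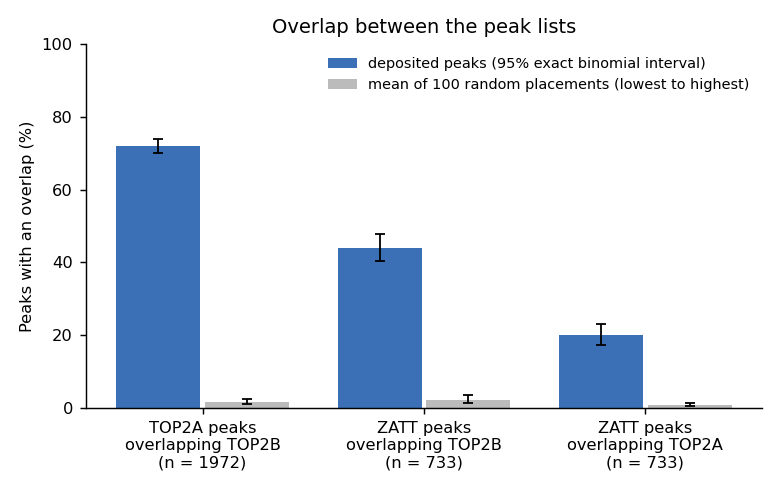
The share of peaks (%) of 1 list that overlapped a peak of another by at least 1 bp is shown for the deposited peaks (coloured bars, with exact 95% binomial intervals) and for 100 random placements (grey bars, mean with lowest and highest). The observed shares were 72.0%, 44.1% and 20.1%, against random means of 1.66%, 2.24% and 0.89%.

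ZATT was next set beside each topoisomerase, since the study asks how ZATT acts on TOP2B in the estrogen response. Of the 733 ZATT peaks, 323 overlapped a TOP2B peak, a share of 44.1% (40.4 to 47.8) and 19.7-fold above the 2.24% of random placement. A TOP2A peak overlapped 147 ZATT peaks, a share of 20.1% (17.2 to 23.1) and 22.6-fold above the 0.89% of random placement. The random values were again set in good part by the 8 mitochondrial ZATT peaks. On the nuclear chromosomes, 315 of 725 ZATT peaks met TOP2B, against 10.5 after random placement, and 139 met TOP2A, against a mean of 0.55, too few for a firm fold. By class, 194 ZATT peaks (26.5%) met the TOP2B list without the TOP2A list and 129 (17.6%) met both lists. A further 18 (2.46%) met the TOP2A list without the TOP2B list and 392 (53.5%) met neither. Most peaks of the TOP2A list carry a TOP2B name, so these classes describe lists and not enzymes. The 410 ZATT peaks with no TOP2B overlap lay at a median of 5.20 kb from the nearest TOP2B peak, against 27.7 kb after random placement. The overlap with TOP2A rested mostly on loci present in all 3 lists. Their removal takes out most shared peaks by construction, and after it 16 of 599 ZATT peaks (2.67%) met a TOP2A peak. With only the call set named for TOP2A, 84 of the 733 ZATT peaks (11.5%) met a TOP2A peak, and with only the smaller TOP2B call set 82 (11.2%) met a TOP2B peak.

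The strongest ZATT sites were found with and without topoisomerase peaks. Among the 10 loci with the highest ZATT scores, 9 also had TOP2A and TOP2B peaks. Most of these 9 loci lay near centromeres or on the mitochondrial genome. The highest of these lay beside centromeres, at chromosome 1 position 121484057 to 121485575 with a ZATT fold enrichment of 6.68 and at chromosome 7 position 61968688 to 61969733 with a ZATT fold enrichment of 7.39. Chromosome 8 position 110346074 to 110347107 was also among the 10, while its score of 17 in each topoisomerase list was below the median of 20 of that list. The locus at chromosome 1 position 156736694 to 156737713, with a ZATT fold enrichment of 6.74, likewise had a score of 17 in the TOP2B list. The strongest ZATT locus with no topoisomerase peak was at chromosome 12 position 6961116 to 6962087, with a fold enrichment of 7.45. It was followed by chromosome 16 position 67840276 to 67841051 (6.80) and chromosome 19 position 4791240 to 4791895 (7.65). Of the loci with ZATT and TOP2B but no TOP2A, the strongest by ZATT score lay on chromosome 12, at position 96428772 to 96430108 with a ZATT fold enrichment of 5.82. These last 2 groups of loci were chosen after their values had been seen.

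The ZATT list allowed vehicle and E2 cells to be compared by position. Of the 366 vehicle peaks, 266 overlapped an E2 peak (72.7%, 67.8 to 77.2), and 267 of the 367 E2 peaks overlapped a vehicle peak (72.8%, 67.9 to 77.2). Random placement of the vehicle peaks gave 0.771%, and 0.0138% on the nuclear chromosomes. The peaks joined into 466 loci, of which 266 had a peak in each condition, 100 in vehicle cells alone and 100 in E2 cells alone. Peaks present in 1 condition alone had lower scores, with a median of 21 against 42 for the shared peaks in vehicle cells and 25 against 45 in E2 cells. The share of vehicle peaks found again in E2 cells was 34.8% (25.2 to 45.4) among the 92 lowest-scoring peaks and 98.9% (94.1 to 100.0) among the 92 highest. For E2 peaks it was 42.4% (32.2 to 53.1) and 94.6% (87.8 to 98.2). The highest-scoring peak seen in vehicle cells alone was at chromosome 3 position 169939822 to 169940176 with a score of 64, and the highest seen in E2 cells alone was at chromosome 4 position 191043745 to 191044256 with a score of 82, while the highest scores of the sets were 991 and 1010. Across the 266 shared loci, which are not independent replicates, the vehicle and E2 scores had a Spearman rho of 0.653. TOP2B peaks overlapped 47.4% of the shared vehicle peaks (41.2 to 53.6), 38.0% of the peaks in vehicle cells alone (28.5 to 48.3) and 32.0% of those in E2 cells alone (23.02 to 42.1). With 1 library per condition, whether a peak that was called in 1 condition alone was gained or lost with E2 could not be tested.

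**Figure D2:**
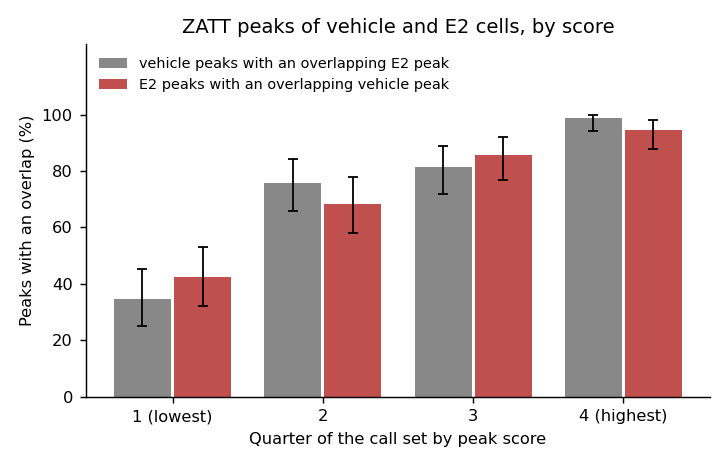
The share of ZATT peaks (%) of each condition that overlapped a peak of the other condition is shown for 4 equal groups of peaks by score, from lowest to highest, with exact 95% binomial intervals. The bars rise from 34.8% to 98.9% for vehicle peaks (grey) and from 42.4% to 94.6% for E2 peaks (red).

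Joining of all peaks gave 43127 loci, of which 81 had peaks of TOP2A, TOP2B and ZATT and 35 had a peak in each of the 6 call sets. Chromosome 17 held 15 of the 81 loci, chromosome 1 held 10, chromosome 20 held 9 and chromosome 10 held 8. A further 1158 loci had TOP2A and TOP2B peaks alone, 121 had ZATT and TOP2B peaks alone and 11 had ZATT and TOP2A peaks alone. Among the 10 of these loci with the highest ZATT scores, besides those already described on chromosomes 1, 7 and 8, were chromosome 19 position 27731811 to 27733465, chromosome 6 position 58776495 to 58779338, chromosome 18 position 18518736 to 18519575 and chromosome 10 positions 42384266 to 42385623 and 42596696 to 42597314. ZATT fold enrichments at these loci were 4.88, 3.34, 8.46, 5.80 and 5.31, and these 5 lay near centromeres, whereas the locus on chromosome 8 did not. The mitochondrial genome had 3 of the 81 loci, among them positions 9 to 3952 with a ZATT fold enrichment of 2.19.

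TOP2B peaks that coincided with TOP2A or ZATT were wider than the rest and somewhat higher in score. A wider peak meets an overlap of 1 bp more easily, so the difference in width is partly built into the definition. The 1614 shared TOP2B peaks, 3.78% of the list (3.61 to 3.97), had a median score of 22 against 19 for the other 41040 peaks, and a median width of 486 bp against 241 bp. Their median fold enrichment was lower, at 3.28 against 3.57. A shared peak ranked above an unshared one in score with a probability of 0.583 (bootstrap interval 0.570 to 0.596) and in width with a probability of 0.781. In score this probability was 0.598 for the 1488 peaks shared with TOP2A and 0.650 for the 258 shared with ZATT, whose median score was 25.5 against 20 for the peaks without ZATT. The values were lower within the larger TOP2B call set, at 0.568 for TOP2A and 0.578 for ZATT, where the median score was 22 at peaks shared with ZATT against 20 at the others. Within the larger TOP2B call set, split into 10 groups of 4238 peaks by score, TOP2A overlap did not rise steadily with score. It was 1.56% (1.21 to 1.98) in the lowest group, 4.15% (3.57 to 4.80) in the sixth from below, 2.31% (1.88 to 2.81) in the second highest and 4.86% (4.23 to 5.55) in the highest.

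The peaks were unevenly spread over the chromosomes, with both topoisomerase lists densest on chromosomes 17 and 20 and the ZATT list on chromosome 19. TOP2B peaks were densest on chromosome 20, with 24.5 peaks per Mb (23.3 to 25.8), followed by chromosome 17 with 22.97 (21.9 to 24.0) and chromosome 19 with 20.6 (19.5 to 21.8), against 14.1 over all chromosomes. TOP2A peaks had 2.02 per Mb (1.72 to 2.36) on chromosome 17 and 1.92 (1.60 to 2.30) on chromosome 20, against 0.635 over all, and the intervals of these chromosomes overlapped. In the set named TOP2A_n1, chromosome 20 was 4.95-fold and chromosome 17 was 4.24-fold above the density over all. ZATT peaks were densest on chromosome 19, the most gene-dense human chromosome, with 1.24 per Mb (0.969 to 1.55), which was 5.18-fold above the 0.239 over all. Chromosome X had the lowest density of each list, with 5.95, 0.110 and 0.0258 peaks per Mb for TOP2B, TOP2A and ZATT. The 1 Mb windows with the most TOP2B peaks lay on chromosome 20 from 52 to 53 Mb, with 122 peaks, and on chromosome 17 from 58 to 59 Mb, with 84 peaks. The same windows held 22 and 23 TOP2A peaks, but they were not the fullest of the TOP2A list. Its fullest windows lay on chromosome 4 from 49 to 50 Mb (34 peaks) and chromosome 10 from 42 to 43 Mb (29 peaks). Chromosome Y from 13 to 14 Mb came next (27 peaks). In TOP2A_n1, the windows on chromosomes 10 and 4 were also the fullest, with 12 and 11 peaks. Chromosomes 17 and 20 carry gained DNA in MCF-7, and the density was not corrected for copy number.

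**Figure D3:**
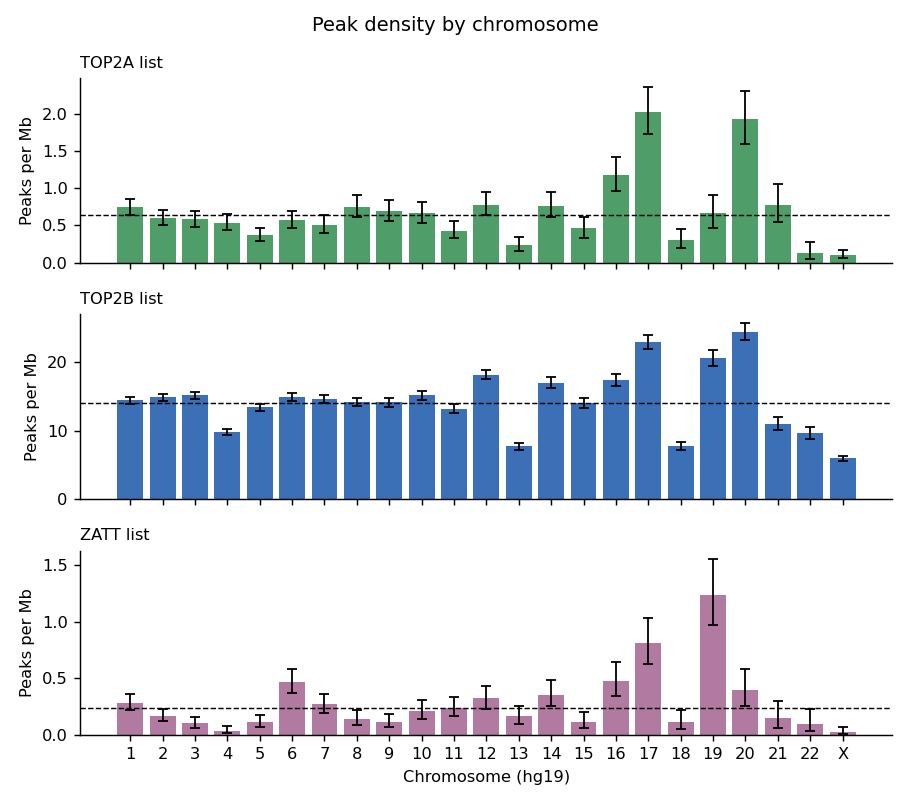
Peaks per Mb are shown for each chromosome of hg19 in the TOP2A, TOP2B and ZATT lists, with exact 95% Poisson intervals and the density over all chromosomes as a dashed line. TOP2A reached 2.02 per Mb on chromosome 17, TOP2B 24.5 on chromosome 20 and ZATT 1.24 on chromosome 19.

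ZATT peaks were most crowded on the short arm of chromosome 6, a region known for its large histone and transfer RNA gene clusters. The 3 windows of 1 Mb with the most ZATT peaks in the genome were those from 28 to 29 Mb (26 peaks), 26 to 27 Mb (17 peaks) and 27 to 28 Mb (17 peaks) of this chromosome. The region from 26 to 29 Mb held 30 vehicle peaks, 8.20% of the set (5.598 to 11.5), and 30 E2 peaks, 8.17% of the set (5.58 to 11.5). In each set 23 of the 30 peaks overlapped a peak of the other condition. TOP2B peaks overlapped 13 of the 30 vehicle peaks (43.3%, 25.5 to 62.6), against 44.9% (39.5 to 50.4) of the vehicle peaks elsewhere, and a TOP2A peak overlapped 1. The topoisomerase lists were denser here too. The TOP2B list had 137 peaks in the region, or 45.7 per Mb against 14.1 over all chromosomes, and the TOP2A list 8, or 2.67 per Mb against 0.635.

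**Figure D4:**
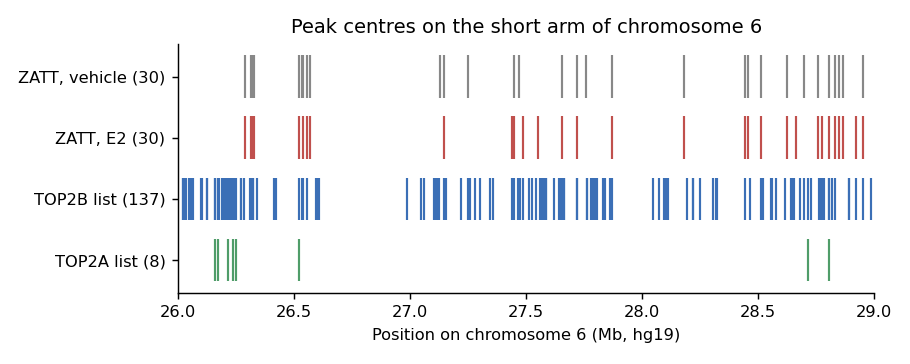
Centres of the peaks between 26 and 29 Mb of chromosome 6 (hg19) are drawn as vertical lines, 1 row per peak set. The vehicle and E2 ZATT rows hold 30 peaks each, the TOP2B row 137 and the TOP2A row 8.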

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

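The mitochondrial genome and chromosome Y, which were left out of the densities per chromosome, held peaks in excess of the 3 counts that a count of 0 allows. The mitochondrial genome held 10 TOP2A peaks, 12 TOP2B peaks and 8 ZATT peaks, and their median fold enrichment was low, between 1.78 in the vehicle ZATT set and 2.21 in the larger TOP2B set. Chromosome Y held 37 peaks in the TOP2A list and 32 in the TOP2B list. In the TOP2A list, 27 of these 37 lay in the window from 13 to 14 Mb. Most chromosome Y peaks overlapped a peak of another list. They were 12 of 13 in TOP2A_n1, 17 of 24 in TOP2B_n2, 9 of 9 in the smaller TOP2B set and 17 of 23 in the larger. Of the 81 loci with peaks of all 3 lists, 1 lay on chromosome Y. Whether these peaks mark binding was not tested.

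The loci with peaks in the TOP2A, TOP2B and ZATT lists alike were examined for technical origins, and no biological explanation was tested. Reads from repeated sequence piling up at single places of the reference may raise peaks in every library, with a lower fold enrichment than other peaks of the same score. The median ratio of fold enrichment to that of score-matched TOP2B peaks was 0.755 (0.626 to 0.864, 87 peaks), but 0.884 (0.705 to 0.983) without chromosomes 1, 17 and 20. It was 0.824 (0.708 to 0.925) in TOP2B_n2, 0.833 (0.735 to 1.05) in TOP2A_n1 and 0.986 (0.884 to 1.09) in the vehicle ZATT set. The same lowered fold was looked for below as a mark of extra DNA copies. The ratio therefore cannot tell repeated sequence from extra copies, and repeated sequence stays open. Extra DNA copies of parts of chromosomes 1, 17 and 20 stay open as well, since these chromosomes held 42.0% of the 81 loci (31.1 to 53.5), an interval that spans 50%, against 16.3% of the other loci. The values without those chromosomes and in the other call sets were computed after the first result was seen. So were those given next for the fullest windows of other chromosomes and for peaks outside the fullest windows.

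The high density of TOP2B peaks on chromosomes 20 and 17 was set against copy number and gene content. For gene-rich chromosomes holding more peaks, the test was chosen after the densities were seen, so its outcome was already known. In the larger TOP2B set chromosome 20 had 23.9 peaks per Mb (22.7 to 25.1), against 20.5 (19.4 to 21.7) on gene-dense chromosome 19. This order is not that of gene density. It cannot weigh gene content as a cause, since chromosome 20 was picked as the densest. Gene content stays open for chromosome 20 and for chromosome 17, whose 22.5 peaks per Mb (21.5 to 23.6) had an interval that overlapped that of chromosome 19. Extra DNA copies of parts of chromosomes 17 and 20 remain a candidate explanation for their 10 fullest windows. Peaks there had 0.647 of the fold enrichment of score-matched peaks on other chromosomes (0.624 to 0.674, 683 peaks), against 0.8997 (0.888 to 0.909) in the 10 fullest windows of those other chromosomes. Outside the 10 fullest windows of chromosomes 17 and 20, the ratio was 0.987 (0.980 to 0.993, 1510 peaks) on chromosome 17. On chromosome 20 it was 0.951 (0.942 to 0.957, 1139 peaks), so the lowered fold lay mainly in the fullest windows. A higher true occupancy in the fullest windows of chromosomes 17 and 20 was not tested.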

How the results depend on the processing

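Each overlap stayed above random placement under every setting of this section. The folds were 23.9 to 57.1 for TOP2A in TOP2B, 14.1 to 29.9 for ZATT in TOP2B and 14.5 to 252.7 for ZATT in TOP2A. These folds depend on whether mitochondrial peaks, which overlap nearly anywhere when placed at random, are included: without the mitochondrial genome they were 57.1, 29.9 and 252.7, the last over a random mean of 0.55 peaks, while the shares stayed within their intervals. Of 76 alternative values, 32 stayed within the interval of the reported value and 44 moved outside it. The 6 density values per chromosome and the shares of vehicle ZATT peaks met by E2 peaks stayed within it. Settings based on single call sets, the mitochondrial genome, joined peaks, loci of all lists, cluster distances and the vehicle to E2 overlap were chosen after the data were seen. The cause of the moves was not tested, except where the setting itself changes the count. Removal of loci in all lists also took out 3 of the 4 mitochondrial loci. Its folds therefore belong beside those without the mitochondrial genome, and each was lower than its counterpart there. For TOP2A in TOP2B, an overlap of at least 50% of the smaller peak gave 63.0% (52.8-fold), centres within 1 kb 80.6% (23.9-fold), the upper 50% by score 62.0%, leaving out chromosomes 1, 17 and 20 69.8%, joined peaks 47.2-fold and removal of loci in all lists 55.0-fold. Only the set named TOP2A_n1 gave 88.2% (25.3-fold), and only TOP2B_n2 48.7-fold. The smaller TOP2B set, which leaves fewer peaks to be met, gave 17.4% (46.6-fold). For ZATT in TOP2B, 50% of the smaller peak gave 34.2%, centres within 1 kb 61.3% (15.7-fold), the upper 50% by score 30.0% (15.4-fold), leaving out chromosomes 1, 17 and 20 40.3% (16.7-fold), removal of loci in all lists 32.2% (22.4-fold) and the smaller TOP2B set 11.2% (14.1-fold). For ZATT in TOP2A, centres within 1 kb gave 27.3-fold, the upper 50% by score 14.5-fold, leaving out chromosomes 1, 17 and 20 15.1-fold, joined peaks 26.7-fold, removal of loci in all lists, which takes out most shared peaks by construction, 2.67% (57.1-fold), and only TOP2A_n1 11.5% (15.3-fold). The probability that a shared TOP2B peak ranked higher was 0.611 with an overlap of at least 50%, 0.781 by width and 0.555 in the larger TOP2B set. Clustered ZATT peaks were 24.0% (vehicle) and 26.5% (E2) within 50 kb, 36.7% and 40.2% within 200 kb, and 26.1% and 26.3% without loci in all lists. Promoter shares, gene lists and sequence motifs were not run because no annotation or sequence of hg19 was used here. No paired analysis was possible because the comparisons between lists and treatments come from no test and the lists are not given per replicate. Depth was unknown, so it could not be told how far the number of weak peaks in each list was limited by it.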

Other observations

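Peaks of the smaller call sets lay close to each other more often than after random placement, and this was not peculiar to ZATT. Another peak of the same set lay within 100 kb for 114 of 362 nuclear vehicle peaks (31.5%, 26.7 to 36.6) and for 118 of 363 E2 peaks (32.5%, 27.7 to 37.6), against 3.91% and 3.96% after random placement (8.05-fold and 8.21-fold). The share was 60.1% in TOP2A_n1 (23.9-fold), 50.4% in the smaller TOP2B set (12.8-fold) and 39.0% in TOP2B_n2 (2.91-fold). The largest vehicle ZATT group was on chromosome 6 from 28625753 to 28950259, with 8 peaks, of which 2 met TOP2B. Groups of 5 peaks lay on chromosome 1 from 161369231 to 161510101, on chromosome 14 from 21077465 to 21152165, on chromosome 17 from 8022598 to 8130373 and on chromosome 6 from 26521426 to 26569241, and none of their peaks met TOP2A. On chromosome 10, by contrast, each of the 4 peaks from 42384972 to 42408554 and of the 4 from 42527782 to 42600211 met TOP2A and TOP2B.

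The pattern of ZATT peaks in clusters, most of all on chromosome 6, was set against gene clusters and repeated sequence. The correlation with protein-coding genes, the partial correlations and the share of unclustered peaks were chosen after the first results were seen. Reads from repeated sequence piling up at single places of the reference stay open. Of the 114 clustered vehicle peaks, 28.1% (20.1 to 37.3) met a TOP2A peak, under the 50% set in advance. That was above the 15.4% (11.1 to 20.5) of the 247 others on chromosomes 1 to 22 and X. The higher share does not describe chromosome 6, where 1 of the 30 vehicle peaks from 26 to 29 Mb met TOP2A and 13 met TOP2B. On chromosome 10, each of the 4 peaks from 42384972 to 42408554 and of the 4 from 42527782 to 42600211 met TOP2A. This split by region was made after the first results were seen. A peak missing from a list of unknown depth excludes nothing, so repeated sequence stays open on chromosome 6 too, without a raised TOP2A share there. A candidate explanation is tRNA gene clusters: over 23 chromosomes, clustered vehicle ZATT peaks and tRNA genes next to another tRNA gene (GRCh38.p14 gene order) had a Spearman rho of 0.722 (permutation p = 0.00016, adjusted over 3 relations 0.000435) and a Pearson r of 0.871 (permutation p = 2e-05), and without chromosomes 6 and 1 rho was 0.635 and r 0.653. Neighbouring protein-coding genes gave a rho of 0.716 (permutation p = 0.00029, adjusted 0.000435) and an r of 0.514 (permutation p = 0.0178), 0.646 and 0.459 without chromosomes 1 and 19, and the partial rho was 0.444 for tRNA genes given protein-coding genes and 0.428 the other way, so general gene density stays open beside tRNA genes. Histone gene clusters gave a rho of 0.287 (permutation p = 0.186, adjusted 0.186) and an r of 0.788 (permutation p = 0.00485) that rested on chromosomes 6 and 1, as without them rho was -0.0967 and r -0.0926, so they cannot be told apart from chance with histone clusters on so few chromosomes.

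The call sets within the topoisomerase lists overlapped across factor names. TOP2B_n2 met a larger share of TOP2A_n1 than of the smaller TOP2B set, but similar shares of its own peaks met each of them. Of the 204 peaks of the set named TOP2A_n1, 197 (96.6%, 93.1 to 98.6) overlapped the set named TOP2B_n2 and 179 (87.7%, 82.4 to 91.9) overlapped TOP2B_nospike, while 142 (69.6%, 62.8 to 75.8) overlapped the smaller TOP2B set. Of the 274 peaks of the smaller TOP2B set, 203 (74.1%, 68.5 to 79.2) overlapped TOP2B_n2. Over the 141 loci found in all 4 topoisomerase sets, which are not independent replicates, the fold enrichments of TOP2A_n1 had a Spearman rho of 0.973 with TOP2B_n2, 0.951 with TOP2B and 0.858 with TOP2B_nospike. TOP2B and TOP2B_nospike had a rho of 0.873. Of the TOP2B_n2 peaks, 10.9% (9.50 to 12.5) met TOP2A_n1, 11.4% (9.93 to 12.9) met the smaller TOP2B set and 69.9% (67.7 to 72.0) met TOP2B_nospike. On the nuclear chromosomes, 189 peaks met TOP2A_n1 against 0.2 after random placement, 197 met the smaller TOP2B set against 0.3, and 1231 met TOP2B_nospike against 21.8. The sets met differ in length, with 204, 274 and 42380 peaks, and these values do not settle which factor TOP2B_n2 holds.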
